A study of Rattus norvegicus with 3 samples.

How the data were processed

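The samples were cultures of NR8383, an established rat alveolar macrophage line that grows in suspension and in loosely attached form. Cells were exposed for 24 h to 1 of 2 kinds of impurity-free single-wall carbon nanotubes, called CNT-1 and CNT-2 in the labels, at 0.1 mg/mL in a solution of 1 mg/mL bovine serum albumin. The labels call the control both untreated and a solvent control with albumin, so it is not settled whether the control cells received albumin. Total RNA was labelled with Cy3 and hybridised to 1-colour Agilent expression arrays, per the labels' protocols. The scans were read with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes. How nanotubes CNT-1 and CNT-2 differ is not given in the sources used here.

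The deposited table held 1 column per group, 3 in all, with 41103 probes and values to 3 decimals. The values were differences on a log2 scale, as deposited by the authors, centred per probe on a baseline that is none of the 3 columns. This was read from the values themselves: they had both signs, their column medians were 0.01 for control, -0.04 for CNT-1 and 0.06 for CNT-2, and the control column lay close to 0 without being exactly 0. The range, from -5.71 to 8.82, rules out a log10 scale, whereas the natural log could not be ruled out and log2 was presumed. All thresholds named as fold changes hold only on that base. The normalization between arrays, the baseline and the direction are not given in the sources used here, and a higher value was taken as more RNA. The study's design text gives an n of 4 without saying of what, and the labels of all samples carry the same replicate number, 4. Whether a column is 1 array or a mean was therefore not settled, and every column was treated as 1 value without replicates.

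Because no group had a second column, no test between conditions was made and no p-value was calculated. The difference between columns was taken per probe, and the value of a gene was the mean over its probes. The spread over the probes of a gene, given as probe SD where a gene had 2 or more probes, is technical spread within these columns and says nothing about the spread between cultures. Its median over genes was 0.08 for CNT-1 minus control, 0.19 for CNT-2 minus control and 0.17 for CNT-2 minus CNT-1. A gene whose value is first given without a probe SD had 1 probe. The number of arrays limits the precision of every value.

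Probes were named through the platform annotation supplied with the values. Of all probes, 20932 had 1 gene symbol, 0 had several and 20171 had none; the last group includes 91 control and quality probes. RefSeq accessions matched to the table of assembly GRCr8 renamed or kept 17424 probes, 3104 kept a platform symbol that is still current, 396 older symbols were updated and 8 stayed unmatched. This gave 15925 genes, 3909 of them with 2 or more probes. No coordinates are given, since the files name no genome build.

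The centring removed the expression level of each probe, which changed the plan made before the data were examined. The planned filter on expression was dropped, as that plan allowed. Random gene lists could not be matched on mean expression. They were matched on the class of the gene in the control column and on having 1 or several probes. A probe was called background-like if its control value lay within 0.02 of the negative-control probe, near 0 if it lay within 0.1 of 0, and other if neither held. Of the gene probes 14.5% were background-like, 72.6% near 0 and 12.9% other. The same classes set the noise of the simulated arrays described below. Alternatives that needed a level were not run, as the closing section says.

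Genes at least 1 log2 unit above or below the compared column were counted, without any claim that they would recur in another culture. For each of 26 gene lists fixed before the data were examined, the median difference was set beside the medians of 10000 random lists of the same size. A list was said to stand apart when its median lay below the 1st or above the 99th percentile. Chance alone would give this for about 0.52 lists per comparison if the members of a list varied independently of each other. Members that vary together between cultures would stand apart more often, which could not be checked with 1 column per group. The percentile of a list describes these arrays only. The lists hold 775 measured genes, and 31 genes stand in more than 1 list. The lists were oxidative stress, metal and iron handling, inflammatory mediators, NF-kappaB feedback and acute phase, inflammasome and pyroptosis, lysosome, autophagy, p53 targets and apoptosis, cell cycle and mitosis, DNA replication, ER stress and integrated stress response, heat shock, cholesterol synthesis and uptake, lipid efflux with PPAR and LXR targets, interferon-stimulated genes, scavenger and phagocytic receptors, hypoxia and glycolysis, matrix remodelling, aryl hydrocarbon receptor targets, cytoskeleton and adhesion, immediate early genes, ribosomal proteins, oxidative phosphorylation, reference genes, alveolar macrophage markers and markers of other lung and blood cells.

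The genes named in the text follow a rule written before the data were examined. It takes the 15 largest differences in each direction per exposure and the 8 largest in each direction for CNT-2 against CNT-1, among genes whose probes all differed one way and whose symbol is not a placeholder. It adds up to 4 members of each list with the largest difference past the threshold in either exposure, and the control genes Gapdh, Actb and Hprt1.

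Both exposures were compared with the same control column, so their differences share its error. The correlation, covariance, shares of same sign and overlap were set beside 200 simulated sets of unchanged arrays sharing 1 control. The noise was taken once from CNT-2 minus CNT-1, an upper bound because it holds real differences, and once from the control column.

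The scripts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The counting and list steps were tested on simulated columns made from the control column, on 15925 genes. In the simulated CNT-1 comparison 50 of 50 genes set 1.5 log2 units higher passed the threshold, as did 49 of 50 set 1.5 lower, 3 of 50 set 0.7 higher and 1 of 50 set 0.7 lower. Of 15725 unchanged genes 104 passed it, or 0.661%. In the simulated CNT-2 comparison a list of 47 genes shifted by 0.3 stood apart, and 0 of 25 lists left in place did. The simulated columns had the narrow spread of the control column (SD over probes 0.16, against 0.40 in CNT-1 and 0.85 in CNT-2) and genes independent of each other. These shares are therefore not rates of false calls in the real comparisons.

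Alternatives fixed before the data were examined were centring of each column on its median or its 75th percentile, quantile normalization of the 3 columns, thresholds of 1.5-fold and 3-fold, and the mean of list members. Alternatives chosen after seeing the data were centring on the E1A spike-in probes, leaving out background-like probes, using only probes near 0 in the control, the median over probes, genes with 2 or more probes only, and the deposited columns without subtracting the control. Subtracting a constant from a column cannot move a list's percentile, so the centrings bear on counts and signs only.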

Results

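Gene expression was measured in NR8383 rat alveolar macrophages, phagocytes of the lung surface grown here as a cell line, after 24 h with either of 2 kinds of single-wall carbon nanotubes or in the control. There was 1 value per probe and group, so no difference below has a replicate check, and "higher" and "lower" describe these arrays only. All values are log2 differences, as presumed from the deposited scale. The median difference over all 15925 genes was -0.04 for CNT-1 and 0.04 for CNT-2 against control, and 0.15 for CNT-2 against CNT-1. Centring on the 75th percentile of each column moved these to -0.04, -0.27 and -0.17, and centring on spike-in probes to 0.003, -0.18 and -0.12. A list described as standing apart did so relative to random lists from the same arrays, a position that these shifts leave in place.

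The first question was how cells exposed to CNT-1 differed from control cells. The clearest group was cholesterol synthesis and uptake, in which 15 of 23 measured members were at least 2-fold higher, none was 2-fold lower and all 23 lay above 0, with a median of 1.66. Tm7sf2, a sterol reductase of the pathway, had the largest positive difference of all named genes at 2.65. Sc5d, a sterol desaturase, was at 2.35, Fdft1, the squalene synthase, at 2.28, and Sqle, the squalene epoxidase, at 2.12. Insig1, a sterol-regulated protein that restrains the pathway's transcription factors, was at 2.20 ± 0.12 (probe SD, 4 probes). The isomerase Idi1 was at 2.08 ± 0.11 and the prenyl synthase Fdps at 1.84 ± 0.08 (probe SD, 2 probes each), and Msmo1, a sterol oxidase, was at 2.01. In total 184 genes were at least 2-fold higher and 342 at least 2-fold lower, so that 35.0% of the genes past the threshold were higher. Quantile normalization turned these counts into 586 and 592, with 49.7% higher. With probes near 0 in the control only they were 128 and 118, with 52.0% higher, and without subtracting the control 247 and 197, with 55.6% higher, so the balance of higher and lower genes in CNT-1 was not settled.

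Further lists stood apart above random lists in CNT-1 with smaller medians and few members past 2-fold. Hypoxia and glycolysis had a median of 0.27 with 1 of 34 members past the threshold, Slc16a3, a lactate exporter, at 1.81. NF-kappaB feedback and acute phase genes had a median of 0.35, with 16 of 18 members above 0 and none past the threshold. Inflammatory mediators had a median of 0.21, with 4 of 36 members higher, among them the cytokine Osm at 1.77 and the neutrophil chemokine Cxcl1 at 1.05, and 1 lower. ER stress and integrated stress response genes lay at 0.13, with none of 34 past the threshold and 29 above 0. The p53 list was at 0.15 with 1 of 28 higher. The oxidative stress list was at 0.13 with 1 of 35 higher, Gstm1 at 1.67, a glutathione transferase. Lysosome genes were at 0.14 with 1 of 47 higher, Atp6v0d2 at 1.07, a proton pump subunit, and cytoskeleton and adhesion genes at 0.11 with none of 40 past the threshold. For comparison, the reference genes had a median of 0.06 without standing apart. The calls for the inflammatory, p53, oxidative stress, lysosome and cytoskeleton lists each ended under at least 1 alternative, whereas those for cholesterol, hypoxia, NF-kappaB and ER stress held under all that were run.

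Lists below random lists in CNT-1 were immediate early genes, with a median of -0.24 and none of 26 members past the threshold, and markers of other lung and blood cells, with a median of -0.20, 1 of 48 members higher and 2 lower. Epcam, an epithelial adhesion protein, was the marker past the threshold on the higher side at 1.61. Neither call held when the mean of members replaced the median. In the control column 10 of these 48 marker genes were background-like, and the negative-control probe itself was at 0.16 in the control column and at -0.11 in the CNT-1 column.

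The lowest genes in CNT-1 were mostly single probes. Prkcq, a protein kinase C of lymphocytes, was at -3.86, Tbpl2, a germ cell transcription factor, at -3.52, Adam26a at -3.07, Ptgfrn at -2.69, Stard10, a lipid transfer protein, at -2.67 and Ptafr, the receptor for platelet-activating factor, at -2.50. The olfactory receptor Or8u8l1 was at -2.67, Ndst1 at -2.44, the actin crosslinker Flnc at -2.41, the hormone gene Rln3 at -2.38, Or7e169c at -2.38, Diras2 at -2.34, Gas7 at -2.33, Fgl1 at -2.33 and Crb2 at -2.23. Prkcq was at -0.996 and Rln3 at 0.96 in the control column, where most probes lie near 0. Of all 342 lower genes 63.7% were neither near 0 nor background-like in the control, against 11.7% of all genes, and with probes near 0 in the control only the count of lower genes was 118. On the higher side, genes outside the sterol pathway included Ltbp1, which binds latent TGF-beta, at 2.46, the lens galectin relative Grifin at 2.47, the olfactory receptor Or12k7 at 2.37, Klhl10 at 2.18, Ccdc96 at 1.95, the muscle protein Csrp3 at 1.93 and Myzap at 1.86. Ltbp1, Myzap, Cxcl1, Or8u8l1 and Flnc were background-like in the control, so the sizes and ranks of their differences depend on the background level.

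**Figure D1:**
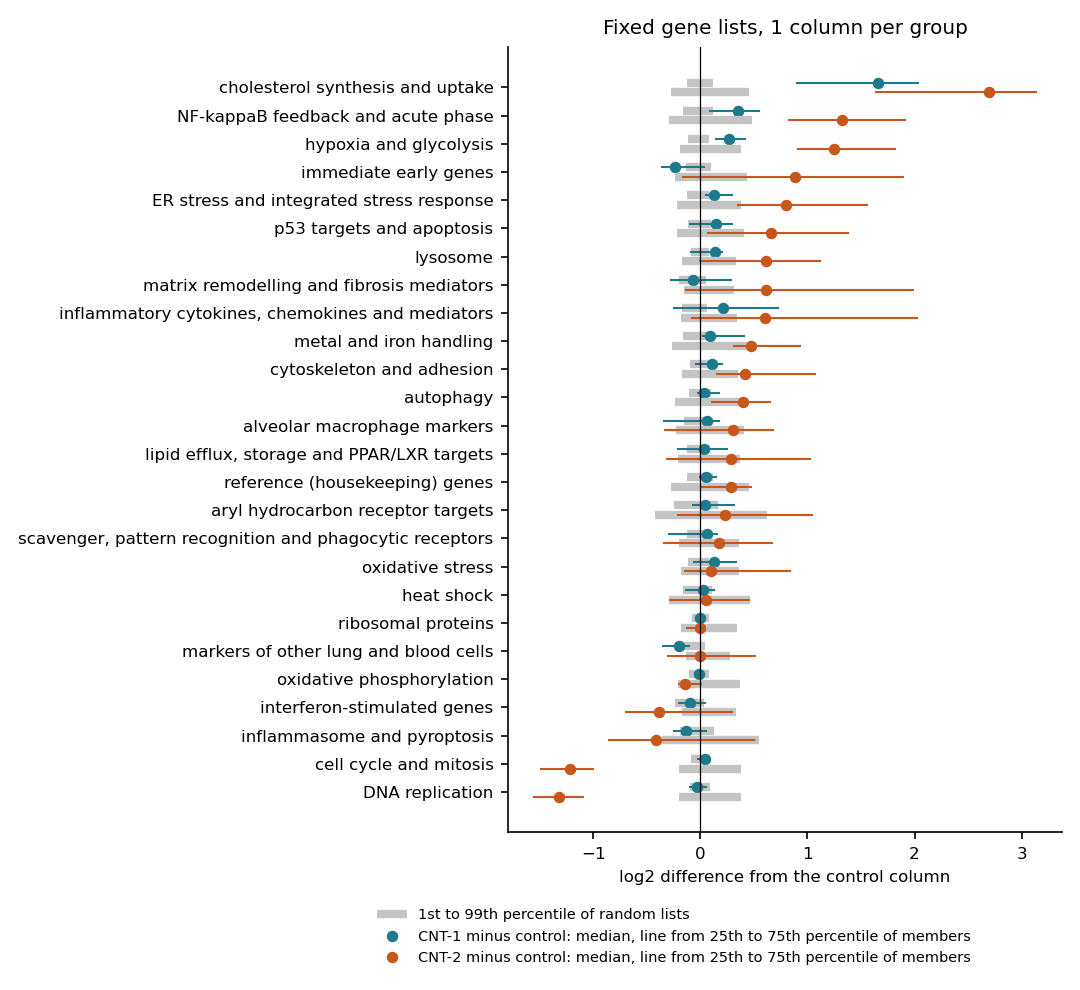
Median log2 difference from the control column (horizontal axis) of the 26 fixed gene lists for CNT-1 and CNT-2, with lines from the 25th to the 75th percentile of the members and grey bars from the 1st to the 99th percentile of 10000 random lists. Cholesterol synthesis and uptake lies at 1.66 in CNT-1 and 2.69 in CNT-2, and DNA replication at -0.03 and -1.32.

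The next question was how cells exposed to CNT-2 differed from the control. Cholesterol genes were again higher, with 21 of 23 members at least 2-fold higher and a median of 2.69. Sc5d was at 3.67, Insig1 at 3.62 ± 0.20 (probe SD, 4 probes), Idi1 at 3.36 ± 0.27 (probe SD, 2 probes) and Msmo1 at 3.22. Genes of cell division were lower. Of 36 cell cycle and mitosis genes 26 were at least 2-fold lower and all 36 lay below 0, with a median of -1.22. Of 34 DNA replication genes 27 were at least 2-fold lower and all 34 lay below 0, with a median of -1.32. Nusap1, a spindle protein, was at -2.13, the DNA topoisomerase Top2a at -1.88 ± 0.07, the spindle checkpoint kinase Ttk at -1.87 ± 0.05 and Melk at -1.72. Among replication factors Mcm10 was at -2.33 ± 0.37, the checkpoint adaptor Clspn at -2.08 ± 0.07, the licensing factor Cdc6 at -1.97 and the helicase subunit Mcm7 at -1.94. Genes with a probe SD here had 2 probes. The same column held a possible sign of RNA quality in the control probes named DCP, whose purpose the files do not give. They were at 0.22 ± 0.08 for numbers 0 to 5 (SD over 11 probes) and at -0.18 ± 0.26 for numbers of 6 and above (SD over 7 probes). The probes with high numbers ranged from -0.54 to 0.20, so not all were low. The split was made after seeing the values.

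The hypoxia and glycolysis, NF-kappaB, inflammatory, ER stress and immediate early lists stood apart above random lists in CNT-2. In the hypoxia and glycolysis list 23 of 34 members were at least 2-fold higher and none lower, with a median of 1.24. Slc16a3 was at 5.71, the glucose transporter Slc2a1 at 2.49, Ankrd37 at 2.38 and the hexokinase Hk1 at 3.82, with a probe SD of 1.56 over 2 probes. NF-kappaB feedback and acute phase genes had a median of 1.32, with 11 of 18 higher and none lower, among them the apoptosis inhibitor Birc3 at 3.24, the adhesion molecules Vcam1 at 2.48 and Icam1 at 2.09, and the inhibitor Nfkbib at 2.36. Of 36 inflammatory mediators 16 were higher and 2 lower, with 13 below 0 and a median of 0.61. The chemokine Cxcl2 was at 6.27, the inducible nitric oxide synthase Nos2 at 4.85, Osm at 4.84 and Cxcl1 at 4.48. Of 34 ER stress and integrated stress response genes 14 were higher and none lower, with a median of 0.80. The glutathione-degrading enzyme Chac1 was at 4.51 ± 0.44 (probe SD, 2 probes), the pseudokinase Trib3 at 3.94, the transcription factor Atf3 at 3.78 and Ppp1r15a, which promotes dephosphorylation of a translation initiation factor, at 3.08. Immediate early genes had a median of 0.88, with 12 of 26 higher and 3 lower. Fosl1 was at 4.90, the phosphatase Dusp1 at 3.32 and Jund at 3.22 ± 0.12 (probe SD, 2 probes). The DCP values given above apply to these groups too, and 10 spike-in probes, which report added RNA, were 0.23 ± 0.10 (SD over probes) above control in this column.

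**Figure D2:**
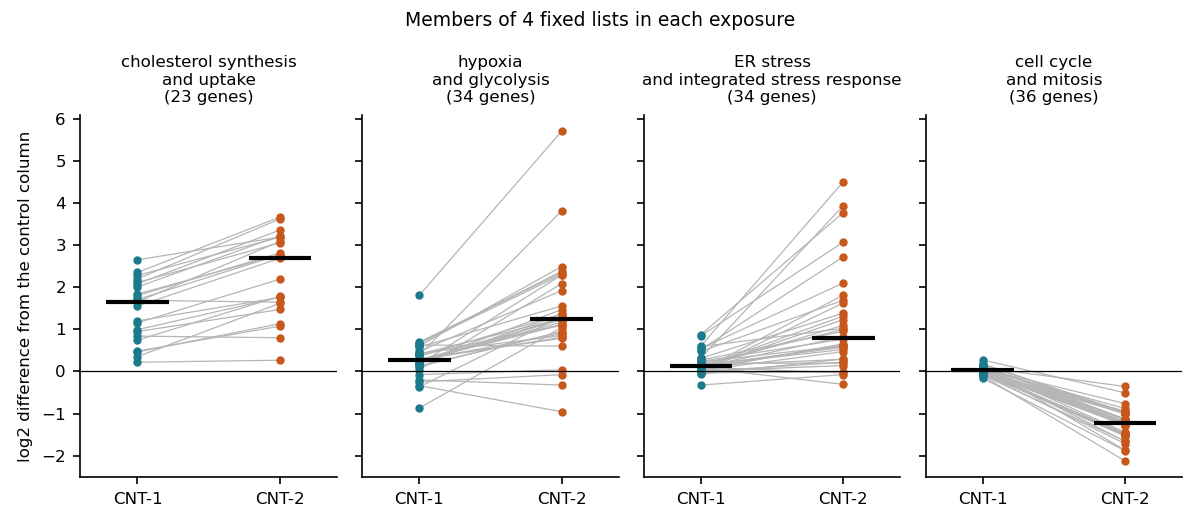
Log2 difference from the control column (vertical axis) of each member of 4 fixed lists in CNT-1 and CNT-2, each gene joined by a line, with black bars at the list medians. All 36 cell cycle genes lie below 0 in CNT-2, with a median of -1.22, against 0.04 in CNT-1.

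Lysosome genes had a median of 0.62 in CNT-2, with 14 of 47 higher and 4 lower. The galactosidase Gla was at 2.39, Atp6v0d2 at 2.25, and the proteases Ctsk and Ctsl at 2.10 and 1.95 ± 0.005 (probe SD, 2 probes). In the p53 list 10 of 28 genes were higher and none lower, with a median of 0.66, including the growth arrest genes Gadd45a at 2.68, Gadd45g at 1.88 and Gadd45b at 1.63 and the repair gene Ddb2 at 2.38. Matrix remodelling genes had a median of 0.61, with 15 of 38 higher and 3 lower. Serpinb2, an inhibitor of plasminogen activators, was at 7.70, the metalloproteinase Mmp10 at 7.11, osteopontin, Spp1, at 4.22 and the growth factor Ereg at 3.93. Cytoskeleton and adhesion genes were at 0.42, with 11 of 40 higher and none lower, such as Actn4 at 1.63, Cd44 at 1.59 ± 0.45 (probe SD, 2 probes) and Cd9 at 1.53. Metal and iron handling genes had a median of 0.47, with 5 of 18 higher and 3 lower, just past the 99th percentile. The siderophore-binding protein Lcn2 was at 3.67, the metallothionein Mt3 at 2.47, the metal transporter Slc11a1 at 2.46 and the metallothionein Mt2A at -1.49. The calls for the p53, matrix, cytoskeleton and metal lists each ended under at least 1 alternative, and with genes of 2 or more probes only the matrix median was -0.17.

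Interferon and inflammasome genes lay below random lists in CNT-2. Of 38 interferon-stimulated genes 8 were at least 2-fold lower and 4 higher, with a median of -0.38. The chemokine Cxcl10 was at -3.70 and the GTPase Ifi47 at -2.71, whereas the deconjugating enzyme Usp18 was at 2.33 ± 0.28 and the antiviral protein Rsad2 at 2.03 ± 0.30 (probe SD, 2 probes each). The inflammasome and pyroptosis list had a median of -0.41 with 3 of 17 higher and 3 lower. Its sensor Nlrp3 was at -2.03 and the thioredoxin inhibitor Txnip at -2.38, while the membrane rupture protein Ninj1 was at 2.52 and the ATP-gated channel P2rx4 at 1.29. The interferon call ended with genes of 2 or more probes only, where the median was -0.03, and the inflammasome call with the mean of members, -0.23.

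Lists that did not stand apart in CNT-2 still held single large differences. In the receptor list the median was 0.17, which became -0.14 with 75th percentile centring, with 6 of 38 higher and 5 lower. Clec4e, a receptor for glycolipids, was at 4.48, the integrin subunit Itgam at 3.46 and the endotoxin co-receptor Cd14 at 3.37 ± 0.16, whereas the Fc receptor Fcgr1a was at -2.56 ± 0.61 (probe SD, 2 probes each). In the list of lipid efflux and storage with PPAR and LXR targets the median was 0.29, or -0.03 with 75th percentile centring, with 10 of 32 higher and 3 lower. The fatty acid binding proteins Fabp4 and Fabp5 were at 3.96 and 2.14, and Angptl4, an inhibitor of lipoprotein lipase, at -3.42. Pdk4 was at -2.68 with a probe SD of 3.41 over 2 probes, which differed in size and not in direction. Autophagy genes were at 0.40 with 6 of 28 higher, among them Bnip3 at 2.30, Tax1bp1 at 1.30, Wipi2 at 1.26 ± 0.01 (probe SD, 2 probes) and the receptor Sqstm1 at 1.83 ± 1.20 (probe SD, 5 probes). Oxidative stress genes had a median of 0.10, or -0.22 with 75th percentile and -0.13 with spike-in centring, with 9 of 35 higher and 1 lower, such as Srxn1 at 1.82 and Sod2 at 1.72. Heat shock genes were at 0.05, or -0.26 and -0.17 under those centrings, with 4 of 21 higher and 1 lower. Hspb1, a small heat shock protein, was at 4.45, Hspa1a at 1.49, Hspa1b at 1.29 ± 1.96 (probe SD, 2 probes) and Cryab at -1.43. Aryl hydrocarbon receptor targets had a median of 0.23, or -0.09 with 75th percentile centring, with 3 of 10 higher, namely Serpinb2, Tiparp at 1.67 and Nqo1 at 1.09, and stood apart only when the mean of members was used.

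Markers and housekeeping lists gave the scale of these values. Alveolar macrophage markers had a median of 0.30 in CNT-2, or -0.01 with 75th percentile centring, with 4 of 26 higher, among them Bhlhe41 at 2.31, and 4 lower. Markers of other lung and blood cells had a median of -0.004, with 4 of 48 higher and 4 lower, among them the proteoglycan Dcn at 2.56, Nkg7 at -1.67 and Vwf at -1.73 ± 1.66 (probe SD, 2 probes). Ribosomal protein genes lay at -0.003, or 0.05 after quantile normalization, -0.32 with 75th percentile and -0.23 with spike-in centring. Oxidative phosphorylation genes lay at -0.14, or 0.007, -0.46 and -0.37 under those scalings. No member of either list was past the threshold in the values reported. The reference genes were at 0.28, or -0.03 with 75th percentile centring, with Pgk1 at 1.10 and Tfrc at 1.03 ± 0.15 (probe SD, 3 probes). Gapdh was at 0.82 ± 0.12 (probe SD, 2 probes) and Hprt1 at 0.49 ± 0.08 (probe SD, 4 probes), while Actb was at 0.24 ± 0.01 (probe SD, 2 probes), or -0.08 with 75th percentile centring. In CNT-1 the lists not yet named did not stand apart in the values reported. Their medians were 0.09 for metal handling, 0.04 for autophagy, 0.04 for the cell cycle, -0.03 for DNA replication, 0.03 for heat shock, 0.03 for lipid efflux, 0.06 for receptors, 0.04 for aryl hydrocarbon receptor targets, 0.06 for alveolar macrophage markers, -0.09 for interferon-stimulated, -0.14 for inflammasome and -0.07 for matrix genes, 0.001 for ribosomal proteins and -0.01 for oxidative phosphorylation. Of these, the DNA replication and oxidative phosphorylation medians turned positive under median, quantile and spike-in scaling, and the matrix median under quantile scaling. With genes of 2 or more probes only, receptors and alveolar macrophage markers stood apart below random lists in CNT-1, at -0.36 and -0.47. Metal and iron handling genes stood apart above random lists in CNT-1 under 3 of 10 alternatives, and matrix genes, at 0.14, with probes near 0 in the control only.

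Among the genes furthest above control in CNT-2, the natriuretic peptide gene Nppb was at 8.12. Also higher were the dopamine transporter Slc6a3 at 7.95, Acod1, which makes itaconate in activated macrophages, at 7.65, Xirp1, an actin-binding muscle protein, at 7.47, Sytl3 at 7.23, the activin subunit Inhba at 6.87 and Eps8, an actin regulator, at 6.73 ± 1.41 (probe SD, 3 probes). Sbsn was at 6.73, Slc2a6 at 6.54, the phosphatase Ptprf at 6.44, Ambp at 6.41, Lat2 at 6.41 and the keratin Krt76 at 6.30. Nppb, Sytl3 and Slc2a6 were background-like in the control, as were Cxcl1, Vcam1, Hk1, Dusp1, Hspa1b and 1 of 2 probes each of Usp18 and Rsad2 among the list members named above, so the sizes and ranks of their differences depend on the background level. On the lower side the succinate receptor Sucnr1 was at -5.57, Clec2l at -4.51 ± 0.20 and the glycogen synthase Gys2 at -4.36 ± 0.32 (probe SD, 2 probes each). The selenium carrier Selenop was at -4.36, Spata46 at -4.33, the cyclooxygenase Ptgs1 at -4.28, the phosphodiesterase Pde9a at -4.14, properdin, Cfp, at -3.83, Abcd2 at -3.67, Igf2 at -3.63, the glutamate transporter Slc1a3 at -3.59 ± 0.04 (probe SD, 2 probes), Pdcd4 at -3.59, the chemokine Ccl12 at -3.50 and Slc36a2 at -3.45. In total 1616 genes were at least 2-fold higher and 1045 at least 2-fold lower, or 60.7% higher among those past the threshold. Centring on the 75th percentile gave 990 and 1837, or 35.0% higher, spike-in centring gave 42.1% higher, and quantile normalization gave 863 and 544, so the balance of higher and lower genes was not settled.

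Set directly against CNT-1, which leaves the control column out, CNT-2 had higher cholesterol genes, with 11 of 23 members at least 2-fold higher and a median of 0.94. Quantile normalization, which gives all columns the same spread, turned that median to -0.70. It moved the list's median against control to 2.34 in CNT-1 and 1.49 in CNT-2. With median, 75th percentile and spike-in centring the median against CNT-1 was 0.835, 0.62 and 0.67. NF-kappaB genes had a median of 1.05 with 10 of 18 higher, hypoxia and glycolysis 0.97 with 16 of 34 higher, immediate early genes 0.94 with 12 of 26 higher and 2 lower, inflammatory mediators 0.83 with 14 of 36 higher and 3 lower, ER stress genes 0.59 with 13 of 34 higher, and matrix genes 0.59 with 14 of 38 higher and 2 lower. The p53 list was at 0.51 with 8 of 28 higher, the lysosome list at 0.48 with 9 of 47 higher and 3 lower, and the cytoskeleton list at 0.39 with 4 of 40 higher. DNA replication at -1.32 and the cell cycle at -1.25 were lower, with 27 of 34 and 29 of 36 members past the threshold, and so were the inflammasome list at -0.58 and interferon-stimulated genes at -0.22. The calls for the NF-kappaB, inflammatory, matrix, p53, lysosome, inflammasome and interferon lists in this comparison each ended under at least 1 alternative. Slc6a3 differed by 8.57, Xirp1 by 8.51, Nppb by 8.01, Mmp10 by 7.79, Acod1 by 7.74, Sbsn by 7.70, Sytl3 by 7.11 and the skin protein Dmkn by 7.09. The lowest were Sucnr1 at -4.69, Ccl12 at -4.18, Pde9a at -3.48, the lectin Clec10a at -3.47, Clec2l at -3.44 ± 0.22 and Gys2 at -3.35 ± 0.35 (probe SD, 2 probes each), the mitotic protein Gtse1 at -3.24 and Spata46 at -3.22. In total 1484 genes were at least 2-fold higher and 740 at least 2-fold lower, or 66.7% higher, against 56.7% with median, 37.7% with 75th percentile and 42.4% with spike-in centring.

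The exposures were then compared in their differences from the control. Among genes past 2-fold, 109 were higher in both and 180 lower in both, against 18.7 and 22.4 for independent lists of those sizes. The genes higher in both included the cholesterol genes Sc5d, Insig1, Idi1 and Msmo1, and those lower in both included Ptgs1, Selenop, Gys2, Cfp and Angptl4, which was at -2.18 in CNT-1. Of the genes higher in CNT-2, 75.6% lay above 0 in CNT-1, and of those lower in CNT-2, 84.8% lay below 0. Over all genes 42.1% lay above and 57.8% below 0 in CNT-1. Simulated unchanged arrays that share 1 control gave 83.7% in both directions with noise from CNT-2 minus CNT-1, and 91.8% and 91.4% with noise from the control column. These simulated columns had equal noise, whereas the deposited columns had SDs over probes of 0.16 (control), 0.40 (CNT-1) and 0.85 (CNT-2). What shares a common control gives at such unequal spreads was therefore not settled. Across genes, which are not independent replicates, Pearson's r was 0.465 and Spearman's rho 0.449. The simulated arrays gave r of 0.501 and rho of 0.482 with noise from CNT-2 minus CNT-1, and r of 0.500 and rho of 0.440 with noise from the control column. The observed r was below both simulated values, and the observed rho lay between them. Equal noise in all simulated columns sets their r near 0.500 by construction, whatever the size of the noise. The deposited columns had unequal SDs, so the simulated r and rho do not show what a shared control alone would give here. No conclusion on the shared control was drawn from r or rho in these simulations. The covariance was 0.160, against 0.301 and 0.0156 in these simulations, a difference of -0.141 or 0.144, whose sign depends on the noise taken. Without subtracting the control column r was 0.461 and the covariance 0.150, so subtracting that column added little to either. The overlap changed more, with 145 genes higher in both and 109 lower in both. With probes near 0 in the control only these counts were 94 and 74, so the number lower in both depends on the control values. Whether the baseline of the deposited values holds the same control is not known. With the first noise the simulations gave on average 503 genes higher in both and 501 lower in both, and with the second 6.27 and 6.36. The first noise alone gave more shared genes than the 109 and 180 observed, so it was too large for these columns. With a single control column the controls could not be split, and part of the overlap may come from the shared control.

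**Figure D3:**
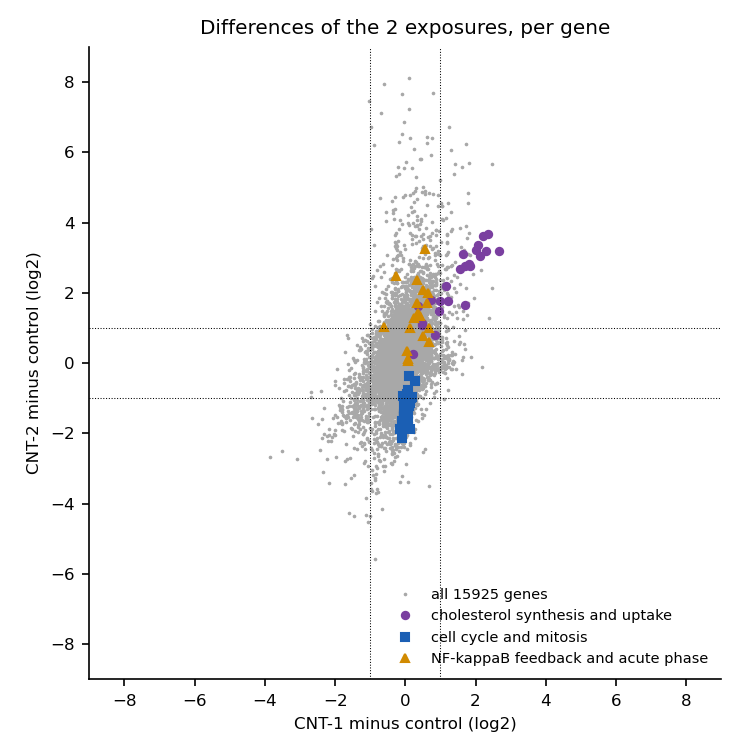
Log2 difference from control of CNT-1 (horizontal axis) and CNT-2 (vertical axis) for each of 15925 genes, with 3 fixed lists in colour and dotted lines at 1 and -1. Cholesterol genes lie to the upper right, with medians of 1.66 and 2.69, and cell cycle genes lie near 0 in CNT-1 and at a median of -1.22 in CNT-2.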

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

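The cell cycle, DCP and control-column tests in this part were chosen after their results had been seen. What the count ratios would show was written down before they were calculated, although spike-in centring and the restriction to probes near 0 were themselves chosen after seeing the data.

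Some signals lay in probes that no comparison used. The 10 E1A spike-in probes averaged 0.225 in CNT-2 minus control, with an SD over probes of 0.103, against -0.05 in CNT-1. The DCP probes with low numbers exceeded those with high numbers by 0.403 in CNT-2 and by 0.057 in CNT-1. Among the 20080 probes without a symbol, 1266 were at least 2-fold higher and 1867 lower in CNT-2, whereas among probes with a symbol 2184 were higher and 1427 lower.

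Some results differed in direction between the exposures, without a test of that difference. Immediate early genes had a median of -0.24 in CNT-1 and 0.88 in CNT-2. At the 2-fold threshold 3 genes differed in opposite directions, named here after their values were seen. Adcy9, an adenylate cyclase, was at -1.01 in CNT-1 and 1.11 in CNT-2, Cyp4a3, a fatty acid hydroxylase with a background-like control value, at 1.10 and -1.02, and Xirp1 at -1.04 and 7.47.

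CNT-2 had 5.06 times as many genes past 2-fold as CNT-1. The tables argue against a shift between the columns, since the lowest ratio over the median, 75th percentile and spike-in centrings was 5.04. They also argue against probes whose control value lay away from the baseline, since the ratio among probes near 0 in the control was 8.62. That class does not give the signal level, so probes near background could not be excluded as a source. A wider scale of the whole CNT-2 column would keep a list near 0 near 0, but cell cycle genes went from 0.04 in CNT-1 to -1.22 in CNT-2. This shows only that the CNT-2 differences were not those of CNT-1 times 1 factor. A wider scale together with a separate difference in these genes could not be excluded. Quantile normalization, which equalises the spread of the columns by construction, brought the ratio to 1.19. A difference in quality or effective dose between the cultures behind these columns stays open, as does a true difference between the nanotubes.

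Partly degraded RNA in the CNT-2 sample could shift many genes at once. Loss of RNA lowers signals, and with spike-in centring 5.48 times as many genes were still higher in CNT-2 as in CNT-1. This argues against loss of signal alone as the source of the higher genes. That degradation can only lower signals was assumed and not checked. The excess of higher genes was much smaller under quantile normalization, which equalises the spread of the columns, with 863 genes higher in CNT-2 and 586 in CNT-1. For the lower genes degradation and a response of the cells cannot be told apart: the DCP difference of 0.403 goes with degradation if the numbers mark positions along a transcript, but the files do not say what they mean. The DCP probes with high numbers also ranged from -0.54 to 0.20 in CNT-2. The lower values of cell cycle and DNA replication genes stay open in this respect.

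The cholesterol genes were higher in both exposures against the same control column, so an error of that column would raise both. It would not raise CNT-2 above CNT-1, where the list lay at percentile 100 of random lists, although quantile normalization turned that median to -0.70. The part common to both exposures cannot be told apart from such an error: the list's median in the control column was -0.00025, close to the baseline, but the sources used here do not say whether the baseline was made from the same control. Both exposures were given in albumin, and whether the control cells received it is not settled. An effect of albumin could therefore not be told apart from one of the nanotubes. An effect of nanotube exposure on sterol synthesis stays a hypothesis.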

How the results depend on the processing

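The median, 75th percentile and quantile scalings, both other thresholds and the mean of members were fixed beforehand; the spike-in centring, the probe subsets, the median over probes and the columns without control subtraction were chosen after seeing the data. Loess on expression, a 75th percentile expression filter, the probe with the highest mean and a floor were not run, since the values hold no level; dropping the filter equals the values reported. No paired analysis was possible because each group had 1 column, and no replicate could be left out. Signal over background could not be read from these values. Of the counts, similarity measures and numbers of lists under alternatives, 122 stayed within 1.5 times the reported value and 49 moved. Centring cannot move the correlations, the covariance or the numbers of lists, so these were among the 122 by construction. The cause of the moves was not tested except where the construction shows it (fewer genes, another threshold, equal spread). With 75th percentile centring CNT-2 had 990 genes higher and 1837 lower, and 838 and 1382 against CNT-1. With spike-in centring it had 915 and 1245 against CNT-1. Quantile normalization gave 586 and 592 for CNT-1, 863 and 544 for CNT-2, 436 and 331 for CNT-2 against CNT-1, 318 higher and 332 lower in both, rho 0.674, covariance 0.244 and 1 list below in CNT-1. At 1.5-fold the counts were 614 and 1024, 3220 and 2193, 3264 and 1695, with 398 and 503 in both. At 3-fold they were 44 and 82, 695 and 349, 558 and 203, with 32 and 34 in both. With the mean of members 0 lists lay below in CNT-1. With probes near 0 in the control only, CNT-1 had 128 higher and 118 lower genes and 74 were lower in both. Genes with 2 or more probes only gave 23 and 36, 342 and 207, 253 and 135, with 17 and 19 in both, 7 lists above and 2 below in CNT-2, and 2 below in CNT-2 against CNT-1. Without subtracting the control, 247 genes were higher and 197 lower in CNT-1, and 145 higher and 109 lower in both.

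Over all lists, comparisons and alternatives the call was the same 706 times, was lost 28 times, was gained 9 times, and 2 further times a list that stood apart had a median of the opposite sign. Median, 75th percentile and spike-in centring gave 78 of the unchanged calls each. A constant cannot move a percentile, so those calls were fixed in advance. Medians of lists that did not stand apart also turned sign under some scalings. Of the lists standing apart, 4 of 11 in CNT-1, 9 of 15 in CNT-2 and 6 of 14 in CNT-2 against CNT-1 did so under every alternative that gave a value. The immediate early, inflammasome and aryl hydrocarbon receptor lists had under 5 members with 2 or more probes and got no value there. Quantile normalization reversed the cholesterol median in CNT-2 against CNT-1 to -0.70, and with it Atp6v0d2 to -0.084, Fabp5 to -0.24, Idi1 to -1.12, Insig1 to -1.13, Ltbp1 to -0.52, Msmo1 to -1.11 and Sc5d to -1.29. Genes below the threshold in that comparison turned too, among them Tm7sf2 to -1.91, Fdft1 to -1.39, Csrp3 to -1.35, Sqle to -1.31 and Fdps to -1.08. It also turned Ndst1 to 0.12 in CNT-1 and 0.98 in CNT-2, and Prkcq to 1.65 in CNT-2, since it widens the narrow control column. With genes of 2 or more probes only the matrix median in CNT-2 was -0.17. Of the named gene values other than those of genes past the threshold that turned sign, 2290 moved by less than the probe SD (or the median probe SD) and 1016 by more. The 2290 include 438 with the median over probes, 402 without background-like probes, 345 with probes near 0 only and 87 with genes of 2 or more probes. Those settings leave a gene with 1 probe unchanged or drop it, so the 2290 do not measure stability.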

Other observations

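The lists in this part, and all tests on them, were chosen after the data had been seen. They were not run under the alternatives, so whether their calls would hold there is not known. Fatty acid synthesis genes had medians of 0.26 in CNT-1 and 1.03 in CNT-2, both above the 99th percentile of random lists. Of 16 measured members 2 were at least 2-fold higher in CNT-1, with 11 above and 5 below 0, and 9 in CNT-2, with 14 above and 2 below 0. Of these members 8 also stand in the fixed lipid efflux list, which did not stand apart in either exposure. Acss2, which makes acetyl-CoA from acetate, was at 1.83 and 3.08, the elongase Elovl6 at 1.52 ± 0.16 and 1.61 ± 0.02 (probe SD, 2 probes), the desaturase Scd2 at 0.77 ± 0.77 and 1.92 ± 1.06 (probe SD, 3 probes), and the synthase Fasn at 0.25 ± 0.49 and 1.66 ± 0.29 (probe SD, 2 probes), in CNT-1 and CNT-2. The probe SD of Scd2 and Fasn in CNT-1 was as large as their differences or larger.

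Amino acid transporters stood apart in CNT-2 with a median of 0.93 and 7 of 16 members at least 2-fold higher, including Slc38a4 at 5.39, Slc6a9 at 3.66, Slc1a4 at 2.99 and Slc38a2 at 2.38 ± 0.19 (probe SD, 2 probes). Aminoacyl-tRNA synthetases did so with a median of 0.54, 4 of 18 higher and 17 above 0, with Aars1 at 1.68 and Cars1 at 1.55. Neither list stood apart in CNT-1, at 0.10 each. In CNT-2 against CNT-1 the transporters stood apart at 0.73, whereas the synthetases, at 0.43, did not. Proteasome subunits stood apart in CNT-1 at 0.11, with 29 of 31 above 0 and none past 2-fold, and not in CNT-2 at 0.29. Complement genes lay below random lists in CNT-1 at -0.27, and at -0.09 in CNT-2 without standing apart. In CNT-2 1 of 17 complement genes was higher, Itgam at 3.46, and 5 were lower, among them Cfp at -3.83, Cfb at -2.13 and C1r at -1.75, with 7 above 0. Class II presentation genes did not stand apart, at -0.07 and 0.20, although Cd74 was at -1.29 and the class II genes RT1-DOa and RT1-DOb, background-like in the control, at 2.61 and 2.12 in CNT-2. Mitochondrial fatty acid oxidation genes were at -0.10 and -0.20 without standing apart.

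A candidate explanation of the higher cholesterol genes is less sterol in the exposed cells, for instance through binding of lipids to the nanotubes. Targets of LXR, a receptor activated by sterols, would then be lower in both exposures. The 10 measured targets had medians of 0.006 in CNT-1 and 0.02 in CNT-2, with 5 above and 5 below 0 in each, and the higher of their percentiles was 52.6. Members went both ways, with Abca1, a cholesterol exporter, at 1.33 and Mylip at -0.95 ± 0.32 (probe SD, 2 probes) in CNT-2, so this test did not decide. Albumin, given with both nanotubes and perhaps not to the control, was not tested as a cause.

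Angptl4 was at -2.18 and -3.42, and Pdk4 at -1.98 and -2.68, with probes that differed in size for Pdk4. Both are induced by fatty acids through PPARs, and less of that signalling may be a cause. The other 15 measured targets had medians of 0.05 in CNT-1 and -0.18 in CNT-2, and the higher of their percentiles was 80.5, with 8 and 6 of them above 0. They went both ways, so this test did not decide either. An effect of albumin was not tested here either.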
